A study of Mus musculus with 6 samples.

How the data were processed

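RNA from sorted splenic NK cells of C57Bl/6 mice was measured on 6 one-colour Illumina bead arrays, 3 of Kit+ and 3 of Kit- cells. Per the labels' protocols, splenocytes were enriched for CD3-negative NK1.1-positive cells by magnetic separation, stained for CD117 and NK1.1, and sorted, with a stated high purity. RNA was amplified and labelled with biotin. The deposited array tables hold raw probe intensity on a linear scale, per the file headers, for 45988 probes on each array and with no detection p-value. Per the submitters' processing notes, BeadStudio 3.1.1.0 was used. The deposited value table of the series also holds intensity on a linear scale. Its column medians were all 92.78, and it matched a quantile normalization of the raw intensities with no background correction, with differences of at most 0.000223 of a value, so its scale is linear, it is not centred, and its direction is that of the raw intensity. It was used as an alternative.

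The design fixed before the data were examined called for neqc with negative controls inferred from detection p-values. Without those p-values, the intensities were corrected with limma's normexp method (offset 50), put on the log2 scale and quantile normalized. Probes were kept where the mean over the 6 arrays lay above the median of all probes, which left 22994. Probe names came from GEO's platform annotation, which can be old: 29457 probes had 1 gene symbol, 11 had several and 16520 had none listed. Symbols were updated through the gene ID against a RefSeq table of assembly GRCm38.p6, which held 29399 of the 29457, and no coordinates are given since the files name no build. No gene was named from a probe with several symbols. A gene was represented by its brightest kept probe, which gave 11743 genes. Of these, 3430 had more than 1 kept probe, and for 1772 another kept probe had the opposite sign, as it did for 18 of the 54 called genes with more than 1.

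The background level was set after the data were seen, as the 95th percentile of 1178 olfactory and vomeronasal receptor probes on each array. It lay between 6.58 and 7.23 on the normalized log2 scale. Where a group was below it on all 3 arrays, the fold is given as a lower bound: the mean of the brighter group against the mean of the background levels of the dimmer group's arrays. The bound is also given where the dimmer group was above it on 1 of 3 arrays, with that array at its own value, and for Prc1, where it was above on 2; for the other named genes past the threshold above it on 2 of 3 the number of arrays is stated. The number of arrays limits the precision, and p-values measure the spread between these samples from separate sorts.

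Groups were compared with lmFit and eBayes of limma 3.58.1 in R 4.3.3 with no block, on the log2 scale, and p-values were adjusted by the Benjamini-Hochberg method over all tested genes, with a threshold of 0.05. "Blocked" values come from the same fit with the replicate number as a block. The titles number the samples 1 to 3 in both groups. Deviations of same-numbered samples from their group means correlated across genes at 0.635, 0.527 and 0.272, while those of samples with different numbers lay between -0.573 and 0.0843, so the numbers were taken to pair the samples. The fit without a block had been fixed as the main one beforehand, since no statistical method was stated, and was kept. It ignores this pairing, so genes that it does not call may still differ. The fits with a single sample left out ignore the pairing too. The labels give no slide or scan date. Gene lists fixed before the data were examined, 29 in number, 28 of them with at least 5 tested genes, were tested with camera at a preset correlation of 0.01 and adjusted over the 28. Of their 758 symbols, 694 had a probe. A list of Y-linked genes had 1 tested gene, with a log2 fold of 0.04, and was not tested as a list. An estimated correlation, fry and the replicate block were alternatives. With an estimated correlation 1 list passed, with fry 4 (2 of them among the 9 of the preset correlation), with the block 10, and with both the block and an estimated correlation 0.

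Genes named in the text were chosen by a rule fixed before the data were examined: Kit, Klrb1c, Cd3e and Cd274, the 12 largest rises and the 12 largest falls among genes past the threshold in the same direction for all 3 numbers, up to 4 members of each list with the smallest p, and any other member of the primary lists (immature NK, mature NK, cytotoxic granule, immune suppression and checkpoint, cell cycle) past the threshold. Clones and predicted genes were to be counted and not named, and none was among the called genes. Cd27, Mki67, Axl, H2-Aa, Lyz2, Ctss, Apoe, C1qa, C1qb, C1qc, Gzma, Ear3 and Ifitm6 lie outside the rule and were chosen after their values were seen.

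The code was tested on simulated arrays built from the means and spreads of the 11743 genes of this comparison, with 5 runs in which 200 genes changed. Without pairing in the simulation, the fit without a block called 36.4% of genes changed 2-fold and 96% of those changed 4-fold, and 5.14% of its calls were unchanged genes. With pairing, that fit called 34.4% and 96.8% with 0% false calls, and the blocked fit called 93.6% and 100%, with 8.73% of its calls being unchanged genes. A list of 20 genes shifted by 0.5 passed in 5 of 5 runs and an unshifted one in 0. Genes were simulated as independent of one another, so these runs cannot show how often an unshifted list of correlated genes would pass.

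Alternatives covered the background correction, the normalization, the filter on dim probes, the choice of probe, the variance model, array weights, the block and the samples left out. Figures were drawn with matplotlib 3.10.9.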

Results

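Natural killer (NK) cells from the spleens of C57Bl/6 mice were compared by whether they carried CD117, the receptor tyrosine kinase encoded by Kit. Per the labels, the Kit+ group was sorted as CD3-negative, NK1.1-positive cells with CD117 on their surface, and the Kit- group as CD3-negative, NK1.1-positive cells without it. Each group had 3 samples, from sorts that were done 3 times per the labels, and each sample was hybridised to 1 Illumina bead array of 45988 probes. The comparison asks which transcripts set the CD117-bearing NK cells apart, in a series whose title concerns NK cells with immunosuppressive functions. The median raw signal was 130 and 84.4 on the number 1 arrays (Kit- and Kit+), 99.4 and 99.9 on the number 2 arrays, and 68.9 and 74.1 on the number 3 arrays. The bright end differed more, with a raw 99th percentile of 6370 and 4850 on number 1, 1027 and 1355 on number 2, and 1951 and 1516 on number 3. The share of probes above the background level was lowest on Kit- 2, at 15.1%, and highest on Kit- 1, at 29.8%.

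Kit, the gene by which the cells were sorted, was higher in the Kit+ sample of all 3 numbers. Its normalized log2 intensity was 8.34 ± 0.55 (SD, n = 3) in Kit- and 11.17 ± 0.79 (SD, n = 3) in Kit+, a 7.12-fold difference (log2 fold 2.83, SE 0.43, limma adjusted p = 0.031). This checks the labels and is no finding. The value comes from the brightest of 3 Kit probes, and the other 2 were below background on all 6 arrays; with the mean of the 2 kept probes the log2 fold was 1.43 (limma adjusted p = 0.0474). Klrb1c, which encodes NK1.1, stood at 12.04 ± 0.54 in Kit- and 11.44 ± 0.53 in Kit+ (SD, n = 3 each, limma adjusted p = 0.578, blocked 0.0705). It was lower in the Kit+ sample of all 3 numbers. Cd3e stood at 9.02 ± 0.53 and 8.21 ± 0.96 (SD, n = 3 each; limma adjusted p = 0.586), and both Cd3e and Cd3d (9.65 and 11.08) were above background on all 6 arrays. With a single sample left out, the adjusted p of Kit lay between 0.0564 and 0.105 in the 6 limma fits without a block, and with median centring in place of quantile normalization it was 0.185. With the replicate block and all samples, the limma adjusted p of Kit was 0.000618.

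Of 11743 genes tested, 62 were higher and 85 lower in Kit+ at an adjusted p under 0.05 (limma with Benjamini-Hochberg adjustment). Ifitm3, an interferon-induced transmembrane protein, rose 9.44-fold (log2 fold 3.24, SE 0.32, limma adjusted p = 0.0102, n = 3 per group), with Ifitm2 up 6.11-fold and Ifitm1 up 5.99-fold (log2 fold 1.5 for Ifitm1 with the mean of its 3 kept probes). Prf1, the pore-forming protein perforin of cytotoxic granules, showed the largest fall among called genes, 9.09-fold (log2 fold -3.18, SE 0.25, limma adjusted p = 0.00553, n = 3 per group). Ifitm3 was above background on 2 of 3 Kit- arrays and Prf1 on 2 of 3 Kit+ arrays, and with the third array at its background level the folds were 7.43 and 7.61. All 62 risers were higher, and all 85 fallers lower, in the Kit+ sample of each of the 3 numbers. The median log2 fold over all tested genes was 0.03.

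Beside Kit and the 3 Ifitm genes, the 12 largest rises were those of Lst1 (6.62-fold), the Fc receptor gene Fcgr4, the iron exporter Slc40a1 (6.22-fold), the ribonuclease Ear10 (6.12-fold), Mpeg1 (at least 3.93-fold), the interleukin-7 receptor chain Il7r (5.05-fold), the adhesion molecule Vcam1 (4.52-fold) and the protease inhibitor Slpi (at least 3.28-fold). Mpeg1 and Slpi were above background on 1 of 3 Kit- arrays, and Ifitm1, Lst1, Slc40a1, Ear10 and Il7r on 2. Slc40a1, Mpeg1 and Vcam1 also stand in the list of macrophage and monocyte markers. Fcgr4 was not above background on any Kit- array and was at least 5.28-fold higher in Kit+. Ear10 belongs to a family of closely related copies that a probe may not tell apart, so its identity is uncertain. The largest falls after Prf1 were those of the antiproliferative gene Btg1 (6.83-fold), the stress-response transcription factor Atf4 (6.54-fold), Capns1 (6.33-fold), Rbm3 (6.08-fold), the integrin chain Itgb2 (5.9-fold), Pfkp, the inhibitory receptor Klrg1 (5.46-fold), the interferon-gamma receptor chain Ifngr1 (4.81-fold), Arf5 (at least 3.93-fold), Ppp2r1a (4.73-fold) and the chymase Cma1 (4.54-fold). Pfkp, a glycolytic enzyme, was not above background on any Kit+ array and was at least 3.9-fold lower there. Arf5 was above background on 1 of 3 Kit+ arrays, and Atf4, Capns1 and Ppp2r1a on 2. For Il7r, Atf4 and Pfkp, 1 of the other kept probes had the opposite sign. With the mean of a gene's kept probes, the log2 fold was 0.873 for Il7r, 0.658 for Vcam1 (limma adjusted p = 0.0722 and 0.11), -1.35 for Atf4, -1.33 for Rbm3 and -0.866 for Pfkp (0.0387, 0.0434 and 0.0474). Across the 62 and 85 genes, the less bright group was below background on all of its arrays for 13 and 23.

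Samples of the same number deviated together. With the replicate number as a block, 453 genes were higher and 515 lower, and these held all 62 and all 85. Without Kit- 1, Kit+ 1, Kit- 2, Kit+ 2, Kit- 3 or Kit+ 3, the fit without a block called 76, 36, 32, 30, 6 and 0 genes, and median centring without quantile normalization called 0 (limma; 1303 genes without Kit+ 3 and 736 with median centring at an unadjusted p under 0.05). Of the 39 called genes that the rule names, none passed in all 6 of these fits with a sample left out, and 9 passed in none: Kit, Cd274, Il7r, Arf5, Eomes, S1pr5, Itgal, Nusap1 and Prc1. Such a fit ignores the pairing and also parts a pair, and all 9 passed in the blocked fit of all 6 samples.

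**Figure D1:**
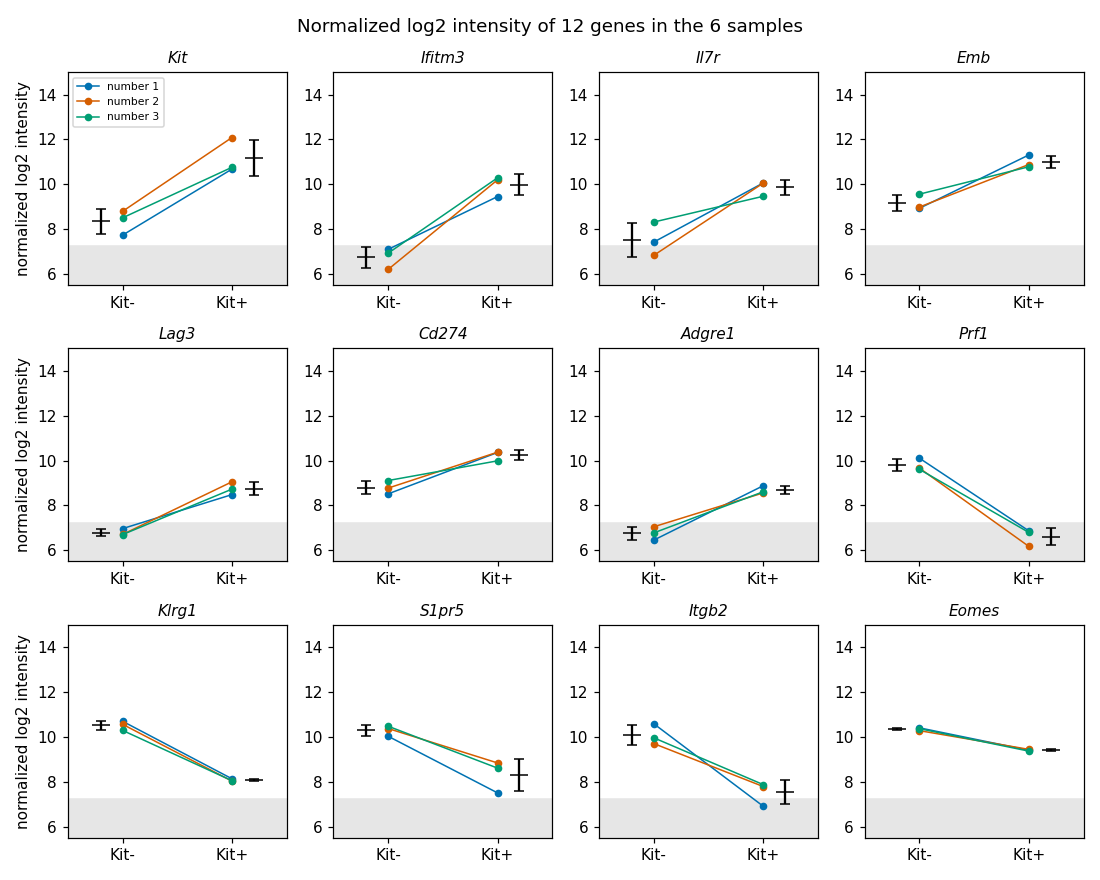
Normalized log2 intensity (vertical axes) of 12 genes in Kit- and Kit+ NK cells, with points for the 6 samples, lines joining samples of the same number, and black bars for the group mean ± SD (n = 3). The grey band ends at the highest array's background level. Kit, Ifitm3, Il7r, Emb, Lag3, Cd274 and Adgre1 were higher in Kit+ for all 3 numbers, and Prf1, Klrg1, S1pr5, Itgb2 and Eomes were lower for all 3.

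Genes of mature NK cells fell as a list and genes of immature NK cells rose. Of 26 tested mature NK genes, 4 fell and none rose (6 fell when adjusted over the list alone, 7 with the replicate block): Prf1, Klrg1, Cma1 and S1pr5. S1pr5, a sphingosine-1-phosphate receptor of circulating NK cells, fell 3.94-fold (log2 fold -1.98, SE 0.35, limma adjusted p = 0.0469), and passed in 0 of 6 fits with a sample left out. The list's median log2 fold was -0.27 (camera adjusted p = 1.89e-05), with adjusted p = 0.0845 with an estimated correlation. Of 23 tested immature NK genes, 2 rose and none fell (5 rose when adjusted over the list alone, 7 with the replicate block): Il7r, and Emb, the surface glycoprotein embigin, which rose 3.56-fold (log2 fold 1.83, SE 0.24, limma adjusted p = 0.0201). That list had a median of 0.39 (camera adjusted p = 0.00138), with adjusted p = 0.353 with an estimated correlation and 0.0593 without Kit- 2, where the median was 0.24. Il7r passed in 0 of 6 fits with a sample left out and Emb in 1. Cd27, an early marker in NK maturation, had a log2 fold of -0.02 (SE 0.36, limma adjusted p = 0.996). Macrophage and monocyte markers moved with the same groups, at a list median of 0.90.

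The Ly49 receptor and NK identity lists fell, the latter with 14 genes above 0 and 15 below. Among 8 tested Ly49 receptor genes, none passed over all genes, 3 fell when adjusted over the list alone, and 2 fell with the replicate block, Klra1 (log2 fold -1.85, SE 0.46, blocked adjusted p = 0.000946 in limma) and Klra4 (log2 fold -2.26, SE 0.47, blocked adjusted p = 0.00433). These genes are near-identical copies, and Klra1 and Klra4 each had 1 of 2 kept probes with the opposite sign. The Ly49 median was -0.53 (camera adjusted p = 0.00167), between -0.747 without Kit+ 3 and -0.317 without both number 1 samples, with adjusted p = 0.311 with an estimated correlation. Of 29 NK identity genes, 1 fell and none rose (5 fell when adjusted over the list alone, 8 with the replicate block). The gene that fell was Eomes, a T-box transcription factor of NK development, at 10.35 ± 0.06 in Kit- and 9.41 ± 0.04 in Kit+ (SD, n = 3 each; limma adjusted p = 0.0445), which passed in 0 of 6 fits with a sample left out and in 6 of 13 under other settings. The companion factor Tbx21 had a log2 fold of -0.94 (SE 0.20, limma adjusted p = 0.0745, blocked 0.0196). The identity list's median was -0.14 (camera adjusted p = 0.0054), with adjusted p = 0.311 with an estimated correlation, and without Kit- 1 the median was 0.05 and the adjusted p 0.0769. Macrophage and monocyte markers rose in the same comparison, at a list median of 0.90.

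The cytotoxic granule list did not pass in camera, with a median log2 fold of 0.00 over 23 genes (camera adjusted p = 0.44). Its fry adjusted p was 0.0788, and 0.037 with the replicate block. Prf1 was the 1 member that fell, and none rose (1 fell when adjusted over the list alone, 4 with the replicate block). Gzmm had a log2 fold of 0.82 (SE 0.26, limma adjusted p = 0.21), Nkg7 of -0.83 (SE 0.27, limma adjusted p = 0.213, blocked 0.045) and Fasl of -0.96 (SE 0.32, limma adjusted p = 0.23, blocked 0.0119).

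Of 33 tested genes of immune suppression and checkpoints, 2 rose and none fell. Lag3, an inhibitory receptor, rose 3.9-fold (log2 fold 1.97, SE 0.21, limma adjusted p = 0.0102). Cd274, which encodes the checkpoint ligand PD-L1, rose 2.72-fold, from 8.80 ± 0.30 to 10.24 ± 0.22 (SD, n = 3 each; limma adjusted p = 0.0319). With a sample left out, Cd274 passed in 0 of 6 fits and Lag3, above background on 2 of 3 Kit- arrays, in 4. Adjusted over the list alone, 6 rose and 2 fell, and with the replicate block 7 rose and 2 fell. Ctla4 had a log2 fold of 1.38 (SE 0.32, limma adjusted p = 0.101, blocked 0.00396) and Cd96 of 1.36 (SE 0.26, limma adjusted p = 0.0567, blocked 0.0132). The list as a whole did not pass (median 0.12, camera adjusted p = 0.153), except without Kit- 1 (adjusted p = 0.0368) and in the blocked fit without both number 1 samples (adjusted p = 0.0259). The latter fit holds only the pairs of numbers 2 and 3, which leaves little to estimate the spread from. Macrophage and monocyte markers were higher in the same samples, at a list median of 0.90.

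Single cytokine, receptor and adhesion genes changed while their lists did not pass. Csf2, the cytokine GM-CSF, was the 1 of 25 cytokine and chemokine genes that rose, 2.66-fold (log2 fold 1.41, SE 0.18, limma adjusted p = 0.0185), in 1 of 6 fits with a sample left out, and also when adjusted over the list alone (list median 0.10, camera adjusted p = 0.446). With the replicate block, 2 of them rose and 1 fell. Of 27 cytokine receptor genes, Il7r and Osmr rose and Ifngr1 fell (2 rose and 2 fell when adjusted over the list alone, 4 and 3 with the replicate block; list median 0.00, camera adjusted p = 0.696). Osmr, an oncostatin M receptor chain, was not above background on any Kit- array and was at least 1.91-fold higher in Kit+, a call that held in 1 of 6 fits with a sample left out. Of 29 trafficking and adhesion genes, 3 fell and none rose: Itgb2 and Itgal, which form the integrin LFA-1, by 5.9-fold and 3.05-fold, and S1pr5. With a sample left out, Itgb2 passed in 3 of 6 fits and Itgal in 0. Adjusted over the list alone, 4 fell and 1 rose, and with the replicate block 6 fell and 2 rose. That list had a median of -0.01 (camera adjusted p = 0.0737), and passed in 7 of 22 other camera fits: without Kit- 2 (adjusted p = 0.00518), Kit+ 3 (0.0464) or both number 2 samples (0.00787), with array weights (0.00958), with the mean of all kept probes (0.0392), and with probes above background on all 6 or at least 3 arrays (0.0163 and 0.0402). With an estimated correlation, a camera fit outside the 22, its adjusted p was 0.446.

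Cell cycle genes rose as a list, with a median log2 fold of 0.51 over 47 genes and 39 of them above 0 (camera adjusted p = 1.28e-08), and adjusted p = 0.311 with an estimated correlation. Nusap1 and Prc1, both of the mitotic spindle, rose at least 3.01-fold and at least 3.08-fold (limma adjusted p = 0.0363 and 0.0486), and none fell. They were above background on 1 and 2 of 3 Kit- arrays and passed in 0 of 6 fits with a sample left out, and with the mean of its 2 kept probes the log2 fold of Nusap1 was 0.987 (adjusted p = 0.0519). Adjusted over the list alone 14 rose, and with the replicate block 16 rose. Mki67, the proliferation marker, had a log2 fold of 0.71 (SE 0.38, limma adjusted p = 0.53, blocked 0.0435), and 1 of its 2 kept probes had the opposite sign. Markers of haematopoietic progenitors, many of which express Kit and divide, also rose as a list (median 0.47 over 16 genes, camera adjusted p = 0.00379), with adjusted p = 0.311 with an estimated correlation. None of the 16 passed over all genes, while 5 rose when adjusted over the list alone and 4 with the replicate block. The list has 23 genes on the array, and those not among the 16 were too dim to be tested. Of the 16, 7 were above background on all Kit+ arrays and 1 on all Kit- arrays, and that gene had a log2 fold of -0.61. Another list holds 5 of the 16, as the neutrophil list holds Mpo. Lmo2 had a log2 fold of 1.33 (SE 0.25, limma adjusted p = 0.0556, blocked 0.00344) and Mpo of 1.45 (SE 0.40, limma adjusted p = 0.158, blocked 0.0102).

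Markers of macrophages and monocytes rose more than any other list by median. Of 19 tested, 5 rose and none fell (11 rose when adjusted over the list alone, 9 with the replicate block). They were Slc40a1, Vcam1, Mpeg1, the macrophage surface receptor Adgre1 (at least 3.53-fold, above background on 1 of 3 Kit- arrays, limma adjusted p = 0.0124), and the receptor kinase Axl (above background on 2 of 3 Kit- arrays, log2 fold 1.67, SE 0.26, limma adjusted p = 0.0356). The list's median was 0.90 (camera adjusted p = 5.06e-11), with adjusted p = 0.0436 with an estimated correlation, and this was the 1 list that passed so. With both the replicate block and an estimated correlation, its camera adjusted p was 0.444. The lysozyme gene Lyz2 had a log2 fold of 0.32 (SE 0.31, limma adjusted p = 0.828), and 1 of its 2 kept probes had the opposite sign. Dendritic cell and MHC class II markers rose as a list (median 0.29 over 20 genes, camera adjusted p = 0.00486), with adjusted p = 0.353 with an estimated correlation, and its median lay between 0.124 without Kit+ 3 and 0.659 without Kit+ 1. Batf3, a transcription factor, and Plac8 rose 3.54-fold and 3.4-fold (limma adjusted p = 0.0231 and 0.0464), each in 1 of 6 fits with a sample left out, and the log2 fold of Batf3, above background on 2 of 3 Kit- arrays, was 1.19 with the mean of its 2 kept probes (adjusted p = 0.0706), while 7 rose when adjusted over the list alone and, with the replicate block, 7 rose and 1 fell. H2-Aa, a class II chain, had a log2 fold of 2.07 (SE 0.61, limma adjusted p = 0.179, blocked 0.000618). Neutrophil markers also rose as a list (median 0.37 over 18 genes, camera adjusted p = 0.00761), with adjusted p = 0.368 with an estimated correlation and 0.0598 without Kit+ 3, and its median lay between 0.147 without Kit+ 3 and 0.666 without both number 2 samples. None of the 18 passed over all genes, 4 rose when adjusted over the list alone, and 5 rose with the replicate block. S100a8 had a log2 fold of 2.34 (SE 0.48, limma adjusted p = 0.0711, blocked 0.00136).

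**Figure D2:**
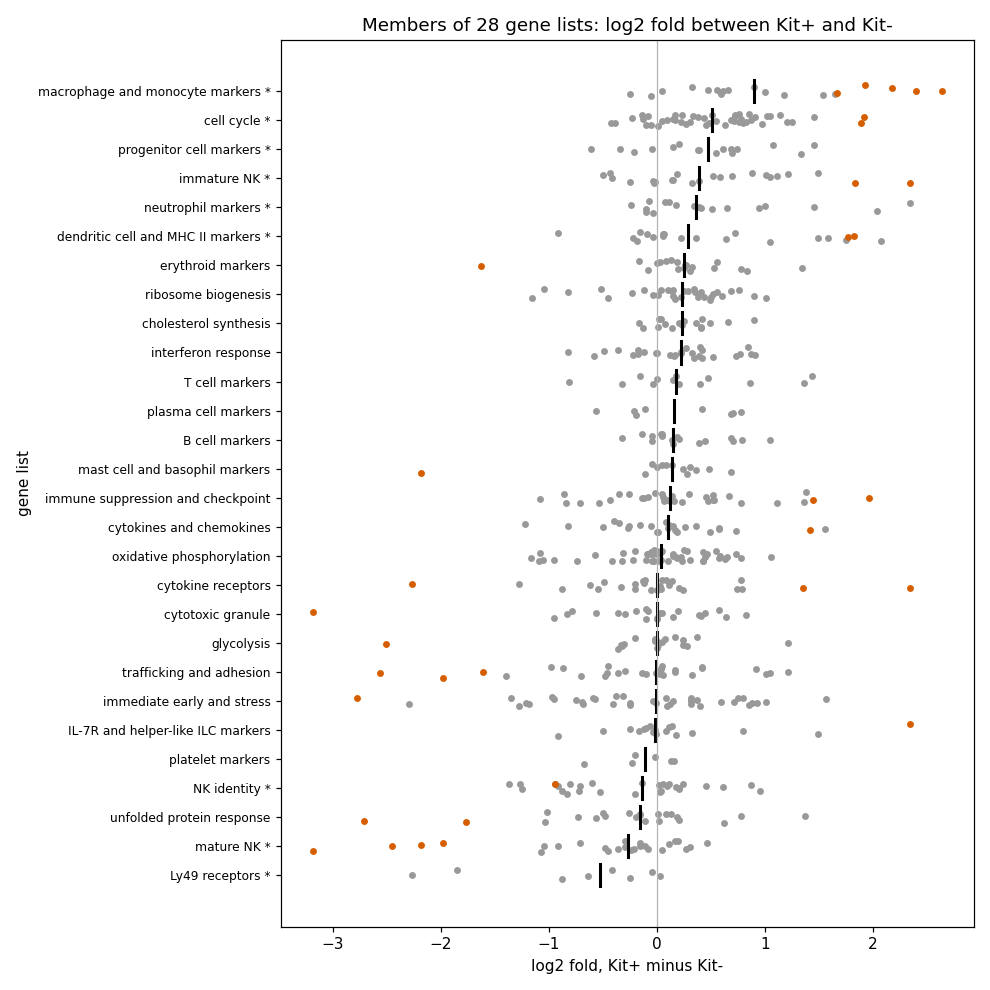
Log2 fold between Kit+ and Kit- (horizontal axis, Kit+ minus Kit-) of the tested members of 28 gene lists (vertical axis), 1 point per gene, orange where the adjusted p over all genes was under 0.05, with a black bar at each list's median. A star marks the 9 lists past the camera threshold with a preset correlation, 6 upward and 3 downward. The macrophage and monocyte markers have the highest median, 0.90, and the Ly49 receptors the lowest, -0.53.

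The remaining marker lists did not pass with camera in the main fit. The median log2 fold was 0.15 over 17 B cell markers (camera adjusted p = 0.318), 0.18 over 13 T cell markers (0.143, and 0.0234 with fry), 0.25 over 19 erythroid markers (0.191, and past the threshold in 4 of 21 other camera fits, with 0.02 without Kit- 2), 0.14 over 13 mast cell and basophil markers (0.446), -0.11 over 6 platelet markers (0.315), -0.02 over 18 markers of helper-like innate lymphoid cells (0.475) and 0.15 over 8 plasma cell markers (0.584). The B cell list passed with array weights (camera adjusted p = 0.0311), and its median lay between -0.0155 without Kit+ 3 and 0.314 without Kit+ 2. The erythroid median was 0.125 without both number 3 samples, and that list had a camera adjusted p of 0.606 with an estimated correlation. Members of these lists past the threshold were Car2, a carbonic anhydrase listed with the erythroid markers, which was not above background on any Kit+ array and was at least 2.5-fold lower there by its brightest probe, Cma1 among the mast cell markers, and Il7r among the innate lymphoid markers. For Car2, 1 of 2 kept probes had the opposite sign, and with the mean of its kept probes the log2 fold was -0.735 (limma adjusted p = 0.633). Each of the 3 was also the only member past it when adjusted over the list alone, where 1 T cell marker joined them. With the replicate block, 3 T cell, 2 B cell, 3 innate lymphoid and 1 plasma cell marker rose. Cd3d had a log2 fold of 1.44 (SE 0.44, limma adjusted p = 0.193, blocked 0.0034).

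Among pathway lists, the unfolded protein response stood nearest to the threshold, with a median log2 fold of -0.15 over 22 genes (camera adjusted p = 0.0542, and 0.0481 with the replicate block; fry adjusted p = 0.00714). Atf4 and Herpud1, which acts in protein degradation at the endoplasmic reticulum, fell, the latter at least 3.2-fold (above background on 1 of 3 Kit+ arrays, limma adjusted p = 0.0319, past the threshold in 1 of 6 fits with a sample left out), while 2 fell and 1 rose when adjusted over the list alone. That list passed in 9 of 22 other camera fits, with an adjusted p of 0.0235 without Kit+ 1 and 0.0432 without Kit- 2. Its adjusted p was 0.311 in camera with an estimated correlation and 0.119 in fry with the replicate block. Its median lay between -0.322 without Kit+ 1 and -0.0475 without Kit+ 3. The median was 0.24 over 32 ribosome biogenesis genes (camera adjusted p = 0.0846), 0.23 over 17 cholesterol synthesis genes (0.0686), 0.22 over 28 interferon response genes (0.143), 0.00 over 19 glycolysis genes (0.446), 0.04 over 50 oxidative phosphorylation genes (0.989) and -0.01 over 39 immediate early and stress genes (0.195). Leaving out a sample took the ribosome list past the threshold without Kit- 3 (adjusted p = 0.0412), the cholesterol list without Kit- 1 or Kit+ 2 (0.0301 and 0.0227), and the stress list, with a lower direction, without Kit+ 1 or Kit- 2 (0.00332 and 0.0022). Pfkp was the only glycolysis gene and Btg1 the only stress gene that fell over all genes, and none of these 6 lists held a gene that rose. Adjusted over the list alone, 1 stress gene rose and 5 fell, and the other 5 lists added none. With the replicate block, 6 stress genes rose and 8 fell, 3 and 4 did so in oxidative phosphorylation, and 2 and 1 in both the ribosome and the interferon lists.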

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

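Of the tests in this part, the counts of other sample splits were planned, and those on macrophage markers and on probes without a gene symbol were chosen after the data were seen.

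Among 6679 kept probes with no gene symbol, which no comparison above uses, 43 differed between Kit+ and Kit- (limma adjusted p under 0.05 over 22994 kept probes). Of these, 13 were higher and 30 lower in Kit+.

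The 6 samples can be split into groups of 3 in 10 ways, too few for a share under 0.05. The real split called 147 genes and the highest of the others 0, so 1 of the 10 splits gave as many (limma; 1537 genes at an unadjusted p under 0.05 against 52 to 1413). Of the 4 splits that part all 3 pairs, the real one called 968 genes with the replicate block and the others 0 (2597 against 88 to 136 at an unadjusted p under 0.05). The 1413 came from a split with both number 1 samples on a side, and the 3 others of that kind gave 341, 584 and 1186. For gene lists the real split had 9 past the camera threshold and the highest of the others 8, so again 1 of the 10 splits gave as many. The split with 8 set both number 1 samples and Kit+ 3 against the rest, while the 3 others with both number 1 samples on a side gave 5, 3 and 2. The 3 other splits that part all 3 pairs gave 1, 6 and 6 lists, and the remaining splits 7 and 6. Several lists thus passed camera at the preset correlation for groupings other than the real one, unlike single genes. Passing this threshold is therefore weak evidence for a list.

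Macrophage and monocyte markers were higher in Kit+, with 17 of 19 tested genes above 0 (of the 19, 5 were above background on all Kit- arrays and none is held by another list). Background correction or normalization as the cause is opposed by the lowest median over 5 other ways, 0.82, with the list past the threshold under each. The 5 are not independent, since all but median centring keep the quantile step. The deposited value table nearly repeats the way with no background correction. A lower share of NK cells, which would raise the markers of every other type alike, cannot be told apart: the median log2 fold of this list exceeded that of 115 markers of 9 other cell types by 0.696 (permutation test over genes, 2-sided, p = 6e-04, with genes taken as independent), but most of these markers are dim, and among those above background on all Kit- arrays, 5 and 25 genes, it did so by 0.14 (p = 1), with dendritic cell markers at 1.49, erythroid at 0.78, T cell at 0.27 and B cell at 0.05 (9, 5, 6 and 3 genes), and plasma cell and progenitor at 0.78 and -0.61 (1 gene each), against 0.62 for this list. That filter leaves out markers that are dim in Kit-, among them the risers Slc40a1, Mpeg1, Adgre1 and Axl. With so few genes left, the filtered test decides little. Macrophages or monocytes among the Kit+ cells may be a source, although magnetic separation and the NK1.1 gate would remove most: of 5 transcripts abundant in macrophages or monocytes and not above background on all 3 Kit- arrays, 1 (Apoe, at 7.22 on the log2 scale) was above it on all 3 Kit+ arrays, while Lyz2, C1qa, C1qb and C1qc, at 6.87, 6.70, 7.12 and 6.93, were not, and Ctss, a sixth, was above it on all 6 arrays. With no pure macrophage sample to show what these probes read, this cannot be told apart from expression of the genes by Kit+ NK cells, which stays open and untested.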

How the results depend on the processing

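Several of these alternatives were chosen after the data were seen: neqc with receptor probes, normexp offset 16, both filters at background, and leaving out a number. Counts of higher and lower genes were 62 and 85. They were 453 and 515 with the replicate block, 310 and 388 with the number as a random effect, 584 and 744 with array weights, and 0 and 0 with median centring without quantile normalization (limma; 736 genes at an unadjusted p under 0.05). The array weights were 6.35 for Kit- 3 and 3.97 for Kit+ 3, against 0.338 to 0.6 for the other arrays. Fits with these weights thus lean on the number 3 pair, and their larger counts are not stronger evidence. Every kept probe on its own gave 186 lower. Probes above background on all 6 arrays gave 21 and 50, among 3995 genes. Without a sample they ranged from 0 to 28 and from 0 to 48, and without a number from 0 to 40 and from 0 to 65. Without replicate 2 or 3 no gene passed (1129 and 996 at an unadjusted p under 0.05). The blocked fit without number 1 gave 486 and 408. It holds only the pairs of numbers 2 and 3, which leaves little to estimate the spread from, and its smallest limma adjusted p was 3.15e-38. Its counts are therefore weak evidence. Fewer samples explain the lower counts in part, and otherwise the cause was not tested. In each fit with 1 value per gene the tested members of the 147 kept their direction, while 18 of the 147 had another kept probe of the opposite sign.

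Of 28 lists, 9 passed. It was 14 with array weights, 1 with an estimated correlation and 4 with fry, of which 2 (mature NK, macrophage) are among the 9 and 2 are not (unfolded protein response, 0.00714, and T cell markers, 0.0234). The immature NK list (median 0.386, and 0.244 to 0.518 with samples left out) had adjusted p = 0.353 with an estimated correlation, 0.0991 with fry and 0.0593 without Kit- 2. The mature NK list (-0.27) had 0.0845 with an estimated correlation, and the cell cycle list (0.51) 0.311 and, with fry, 0.0684. The suppression list (median 0.00342 to 0.254 with samples left out) passed without Kit- 1 and in the blocked fit without number 1 (0.13). Oxidative phosphorylation, not past the threshold, turned upward past it with array weights (median 0.157) and without replicate 1 (0.177, of a range from -0.0049 to 0.182 with samples left out). Apart from the changes given here and in the report, the replicate block changed no list call in camera at the preset correlation. In fry with the block, 3 lists passed: mature NK (adjusted p = 0.037), macrophage and monocyte markers (0.0173) and cytotoxic granule (0.037). Without the block, fry gave the cytotoxic granule list 0.0788. T cell markers had 0.0604 in fry with the block.

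Neqc with detection p-values, its other offset, the stricter detection filter and the slide or scan date were not run, since the files hold no detection p-value, slide or date. Signal over background limits the dim genes: 15.1% to 29.8% of probes lay above it.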

Other observations

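The tests in this part were all chosen after the data were seen. Among 509 gene families defined by a shared symbol stem with at least 4 tested members, the interferon-induced transmembrane family stood out. Of its 5 tested members 4 rose in Kit+ (exact hypergeometric test against the 62 risers among 11743 genes, p = 3.51e-09, Benjamini-Hochberg adjusted p = 3.57e-06 over both directions). Beside Ifitm1, Ifitm2 and Ifitm3, these included Ifitm6, which was not above background on any Kit- array and was at least 2.67-fold higher in Kit+ (limma adjusted p = 0.0102). No other family passed. The hypergeometric test takes genes as independent, and Ifitm1, Ifitm2 and Ifitm3 already stood among the largest rises in the same data. Its p-value is thus no separate support, and whether the probes tell the members of the family apart was not tested. A second ribonuclease of the Ear group, Ear3, above background on 2 of 3 Kit- arrays, rose with a log2 fold of 1.36 (SE 0.20, limma adjusted p = 0.0297), with the same doubt over its copies as Ear10. Of the 62 risers, 47 lay in none of the fixed lists, and of the 85 fallers 72.

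The cytotoxic effector gene Gzma varied more between samples of a group than between groups, at 8.68 ± 2.32 in Kit- and 8.39 ± 2.30 in Kit+ (normalized log2 intensity, SD, n = 3 each; limma adjusted p = 0.981).

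An interferon response would be a candidate explanation for the rise of the 4 Ifitm genes. The 28 other tested interferon response genes had a median log2 fold of 0.224, with a bootstrap interval from -0.00393 to 0.397 over genes (95%, 10000 resamples). That upper bound lies below 0.939, which is 50% of the lowest log2 fold among the 4, so the tested genes as a set rose less than the 4. The limit of 50% was set after the data were seen. Of the list's 39 genes on the array, only 28 were tested, and some of these lay near background. Rsad2, for example, stood at 6.56 in Kit- and 7.29 in Kit+. The test thus cannot exclude an interferon response in part of the list. Background correction or normalization as the source of the rise is opposed, since the lowest log2 fold of the 4 under 5 other ways was 1.73. All of these ways but median centring keep the quantile step. The calls themselves did depend on the normalization. With median centring, 1 of the 5 ways, no gene passed, and the limma adjusted p of Ifitm1, Ifitm2 and Ifitm3 was 0.185. A rise within Kit+ NK cells and a contribution from other cells that carry these transcripts were not tested here and stay open.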
